A study of Mus musculus with 6 samples.

How the data were processed

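Small RNA libraries of mouse brain were made from total RNA extracted with Trizol, per the labels' protocols, and read as single reads on an Illumina NextSeq. The submitters' processing notes name FastQC, cutadapt and Novoalign and the genome build mm10, with no versions. The counting program, the alignment settings, the source of the tDR IDs and the rule for listing a value are not given in the sources used here. The deposited table holds tag counts per tDR ID, per the file headers. Although its title calls it normalized, the values are whole numbers whose totals and smallest non-zero values differ between libraries, and they were treated as raw counts.

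The table has 3257 lines, 1 for each pair of tDR ID and parent tRNA name, and repeats the same counts on every line of an ID, so each of the 591 IDs was counted once. Parent names fall into 336 mature tRNAs, all with a sequence that ends in CCA, and 167 precursors. An ID took the amino acid and anticodon of its parents; 574 IDs have parents of 1 amino acid and 17 are shared, 6 of these between glutamate and lysine, and shared IDs entered no amino acid list. The table gives the sequence of the parent and not of the fragment. Lists by fragment end and length were therefore not analysed here. The table names 0 mitochondrial parents and lists tRNA fragments only, so the planned lists of mitochondrial tRNAs, of miRNAs that mark cell types and of other RNA classes had no members. Fragments of one tRNA overlap, and near-identical gene copies share reads, so IDs are neither independent nor tied to 1 gene.

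The columns are named Age and WT with the numbers 1 to 3. They were read as 22 months and 3 months, replicates 1 to 3, from those names and the ageing design; this is a reading of names that differ from the sample titles. The labels do not say that replicates are separate animals, so p-values measure the spread between these samples. Replicates of one age differed by more than sampling noise (chi-square per degree of freedom between 6.6 and 59.7), and each was counted as 1 sample.

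The smallest non-zero counts are 11, 8 and 9 at 3 months and 13, 17 and 17 at 22 months, which is a CPM of 177 to 204 of the listed tags in every library. A zero was kept as 0 in the main test. A fold against an age at 0 in every library was bounded with the mean of the smallest listed levels of that age, since a count of 0 here is not a true zero. Listed totals between 44156 and 96130 tags limit the precision, and counting error was not set apart from the spread between libraries.

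The comparison of 22 with 3 months used edgeR 4.0.16 (filterByExpr with a minimum count of 10, TMM scaling, quasi-likelihood test without a replicate term) under R 4.3.3, with Benjamini-Hochberg adjustment over the 439 IDs kept; 152 were not tested. CPM of single IDs and of anticodon sums are TMM-scaled, and the listing minimum is given without that scaling. For anticodon sums the total is that of the summed tags, from IDs that name 1 anticodon only. Their CPM are therefore higher than on the scale of single IDs and cannot be set against it or against shares of listed tags. Standard errors are the log2 difference divided by the square root of F. Lists of at least 3 IDs by amino acid were tested with limma 3.58.1 (camera on log2 CPM with a prior count of 2 and a preset correlation of 0.01, repeated with an estimated correlation and with fry). Sums per amino acid, as shares of listed tags, were compared by an exact two-sided permutation test. DESeq2 1.42.0 and limma-voom were alternative tests. Tables were read with pandas 2.3.3 and plots drawn with matplotlib 3.10.9. Sequences and gene coordinates of the parent tRNAs are not reported here.

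The design, the tests and the alternatives in scaling, filter, tool, replicate block, samples left out and summing per anticodon were fixed before the data were examined. Named tDRs were, by a rule also fixed then, the 10 largest rises and 10 largest falls among IDs past the threshold and separated between the ages, the most abundant Glu-CTC and Glu-TTC IDs, the 5 most abundant IDs, and up to 3 most abundant members of each list past the threshold. IDs named outside this rule are said to be. Alternatives added after seeing the data were the restriction to IDs above 0 in all 6 libraries, zeros set to 1 below the smallest listed count, scaling to the smallest listed count, TMM scaling of the amino acid sums, the repeats of the anticodon sums, and lists by mature or precursor parent.

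The test was tried on simulated data for this comparison, 5 simulations of 591 IDs with 200 changed. With the common dispersion of the real data, 0.384, given to every ID, it recovered 0% of 4-fold and 0% of 2-fold changes, with 0 calls in total. The real data gave 29 calls, so a single dispersion for every ID does not describe them. That setting therefore cannot tell which changes the test detects in the real data. At a dispersion of 0.1 for every ID, the test recovered 75.8% of 4-fold and 26.2% of 2-fold changes, with 3.39% false calls.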

Results

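Small RNA was sequenced from the brains of C57BL/6 mice, a common inbred laboratory strain, at 3 months of age (n = 3 libraries) and at 22 months (n = 3 libraries). The values are tag counts of tRNA-derived small RNAs (tDRs), which are fragments cut from mature tRNAs or from their precursors, each with its own ID. The table lists 591 tDR IDs under 503 parent tRNA names. Listed tags summed to 57425, 45131 and 44156 in replicates 1, 2 and 3 at 3 months, and to 71121, 96130 and 84807 in those at 22 months. Each library lists only values above a minimum, between 177 and 204 CPM (tags scaled to a fixed total of listed tags), and gives the rest as 0, so a 0 means a level below that minimum. A total of 290 IDs lay above it in all 6 libraries. All levels are relative to the listed tRNA fragments, because the full library totals are not used here.

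The fragments came mostly from a few tRNAs at both ages. Fragments of lysine tRNAs took 24.2% ± 3.25 (SD, n = 3) of listed tags at 3 months and 22.6% ± 3.17 (SD, n = 3) at 22 months, and fragments of glycine tRNAs took 23.5% ± 2.15 and 29.9% ± 2.77. The most abundant ID, AS-tDR-007295 of Lys-CTT, made up 15.4%, 22.3% and 17.8% of the tags in the 3 libraries at 3 months and 13.1% and 15.7% in replicates 1 and 2 at 22 months. In 22 month replicate 3 it had 4723 tags, and the most abundant ID was AS-tDR-007238 with 6.42% of the tags. The log2 difference of AS-tDR-007295 between 22 and 3 months was -0.48 (SE 0.44), not past the threshold (edgeR quasi-likelihood test, adjusted p = 0.553). The next most abundant were AS-tDR-007238, AS-tDR-000011 and AS-tDR-001297, all of Gly-CCC and Gly-GCC parents, with log2 differences of 0.49, 0.52 and 0.75, and AS-tDR-001360 of Lys-CTT with 1.48. None of these 4 passed the threshold (edgeR, adjusted p = 0.252, 0.332, 0.282 and 0.206).

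The series asks which tRNA fragments differ between young and aged brain. Among the fragments past the threshold, leucine tRNAs gave 13 of the 21 that rose with age and valine tRNAs 5 of the 8 that fell. Among IDs above the listing minimum in all 6 libraries, a restriction chosen after seeing the data, leucine gave 18 of 38 rises, and valine 7 and methionine 6 of 27 falls. Of 439 IDs tested, 21 rose and 8 fell at 22 months (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). With library size only, with no filter on low counts, with a replicate block, or when scaled to the smallest listed count (chosen after seeing the data), 0 rose and 0 fell. The 21 that rose comprised 13 of leucine, 3 of asparagine, 2 of aspartate and 1 each of alanine, isoleucine and serine tRNAs. The 8 that fell comprised 5 of valine, 2 of aspartate and 1 of glutamate tRNA. All 29 had adjusted p between 0.0489 and 0.049, and no ID passed when any one of 3 month replicate 1, 2 or 3 or of 22 month replicate 1 was left out, against 14 without 22 month replicate 2 and 11 without 22 month replicate 3. All 29 kept their sign in each of those 6 fits, and 112 IDs had an unadjusted p under 0.05, 69 higher and 43 lower, a split of 46 higher and 61 lower when scaled by library size only.

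Among the single fragments that rose, 5 were listed at 0 in every library at 3 months. AS-tDR-001808 and AS-tDR-001809 of Asp-GTC were at least 3.39-fold and at least 2.82-fold higher at 22 months, AS-tDR-015085 of Ser-GCT at least 2.67-fold, AS-tDR-015068 of Asn-GTT at least 2.42-fold and AS-tDR-012735 of Ile-TAT at least 2.1-fold. These bounds are taken against the mean of the smallest listed values at 3 months. The other large rises were all of leucine tRNAs. AS-tDR-011096 of Leu-AAG went from 186 ± 19.2 to 671 ± 179 CPM (SD, n = 3 each), a log2 difference of 1.84 (SE 0.37). Its 3 month tags of 11, 8 and 10 lay at or next to the smallest listed counts, 11, 8 and 9. Its 3 month level and SD are thus those of values at the listing minimum. AS-tDR-015048 of Leu-CAA rose by 1.73 on the log2 scale, AS-tDR-015050 of Leu-TAG by 1.59, AS-tDR-011371 of Leu-AAG by 1.57 and AS-tDR-015047 of Leu-CAA by 1.57. These 10 were higher in all 3 libraries at 22 months than in any at 3 months, which the naming rule requires. Across all tested IDs 39.4% were separated in this way in one direction or the other. Chance gives 10% for a single ID, but the IDs overlap and share the same 6 libraries, so the 39.4% is not a test of age.

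AS-tDR-015065, of Val-AAC and Val-CAC parents, was at 600 ± 48.9 CPM at 3 months (SD, n = 3) and listed at 0 in all 3 libraries at 22 months, at least 2.9-fold lower. AS-tDR-012324, of the same anticodons, fell from 2229 ± 331 to 658 ± 128 CPM (SD, n = 3 each), a log2 difference of -1.76 (SE 0.23). The log2 difference was -1.72 for AS-tDR-009914 of Val-CAC, -1.64 for AS-tDR-009918, listed under a Val-CAC precursor only, and -1.57 for AS-tDR-010620. Outside valine, AS-tDR-011793 and AS-tDR-008906, both listed under 1 Asp-GTC precursor, fell by 1.29 and 1.21 on the log2 scale, and AS-tDR-002583 of Glu-CTC fell by 1.19.

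**Figure D1:**
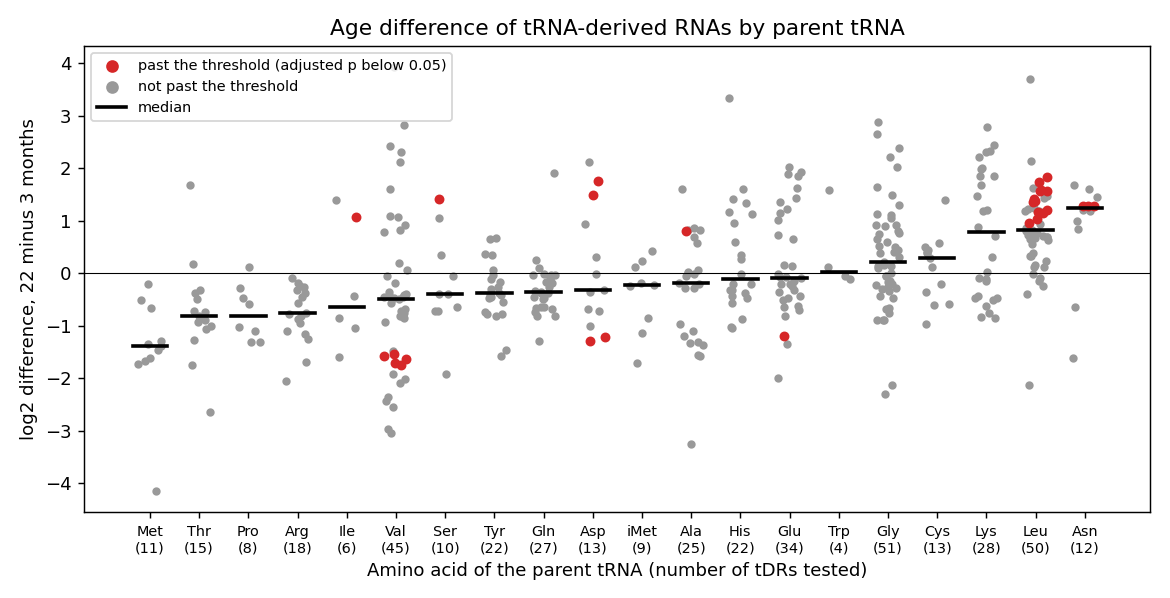
Log2 difference between 22 and 3 months (vertical axis) of each tested tDR, grouped by the amino acid of its parent tRNA, with the number tested in parentheses; red points passed the threshold and bars are medians. IDs at 0 in every library of one age are drawn at their bound. Leucine holds 13 of the red points above 0 and valine 5 below it.

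By amino acid, the lists of leucine and asparagine fragments ranked higher at 22 months, and those of valine, methionine, arginine and threonine lower, in a set test with a preset correlation (limma camera, 20 lists; adjusted p = 5.79e-10 for leucine, 0.00295 for asparagine, 0.000895 for valine, 0.00152 for methionine, 0.0115 for arginine and 0.0303 for threonine). None of these 6 held with an estimated correlation (adjusted p = 0.747 with an estimated correlation for each). The estimates were 0.2485 for leucine, 0.671 for asparagine, 0.036 for valine, 0.687 for methionine, 0.355 for arginine and 0.331 for threonine. All exceed the preset 0.01, so the preset test treats overlapping fragments as nearly independent. The valine estimate lay nearest the preset, yet its unadjusted p went from 8.95e-05 to 0.04 (camera). The size of the correlation alone therefore need not account for the loss of the calls. Among lists that did not pass, lysine had a median log2 difference of 0.79 (camera, adjusted p = 0.18), between 0.33 without 22 month replicate 3 and 1.42 without 22 month replicate 1, where it passed (adjusted p = 0.0227), and proline -0.81 (adjusted p = 0.18). The median log2 difference was 0.85 over 50 leucine IDs, of which 13 rose, 0 fell and 37 did not pass (0.82 with IDs at 0 in one age set to their bound). Adjusted over the list alone, 22 leucine IDs rose and 1 fell. Counts adjusted over a list alone, here and below, leave out the other IDs tested. They do not hold the error rate over all IDs and are descriptive. The most abundant leucine members were AS-tDR-009290 of Leu-TAA, at 10367 ± 2118 and 19767 ± 2002 CPM (SD, n = 3 each; log2 difference 0.93, edgeR adjusted p = 0.0584), AS-tDR-011859 of Leu-CAA and Leu-CAG, at 0.16 (adjusted p = 0.657; -0.04 when scaled by library size only), and AS-tDR-009243 of Leu-TAG, at 0.72 (adjusted p = 0.121). Of 12 asparagine IDs, 3 rose, 0 fell and 9 did not pass, with a median of 1.24, and 7 rose adjusted over the list alone. Their most abundant members AS-tDR-007408, AS-tDR-012678 and AS-tDR-009289 had log2 differences of 0.84, 1.20 and 1.19 and did not pass (edgeR, adjusted p = 0.261, 0.2 and 0.0702).

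All 11 methionine IDs, which here exclude the initiator tRNA, had a negative log2 difference, with a median of -1.39. None passed over all IDs and 7 fell adjusted over the list alone. AS-tDR-004475, AS-tDR-004489 and AS-tDR-004518 had log2 differences of -1.62, -1.29 and -1.39 (edgeR, adjusted p = 0.0582, 0.0527 and 0.0692). AS-tDR-004475 lay at 23608 ± 1468 CPM at 3 months and 7679 ± 3378 at 22 months (SD, n = 3 each). The 7 that fell within the list are listed under the same number of parents, 9, and the stretches of 15 nt or more shared by those parents lie between positions 27 and 55 of the 76 nt Met-CAT-6-1 tRNA, counted from its 5′ end.

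Of 45 valine IDs, 5 fell, 0 rose and 40 did not pass, with a median of -0.57 (-0.50 with IDs at 0 in one age set to their bound), and 7 fell adjusted over the list alone. Summed per anticodon the valine direction turned, to a median of 0.04, with Val-TAC at -0.78, Val-CAC at 0.04 and Val-AAC at 0.79, none past the threshold (edgeR, adjusted p = 0.0853, 0.894 and 0.441). These sums leave out IDs shared between Val-AAC and Val-CAC, 3 of the 5 that fell among them. Their CPM are scaled to the tags of IDs that name 1 anticodon only. In 22 month replicates 1, 2 and 3 the Val-AAC sum was 5267, 9808 and 37450 CPM, against a mean of 10080 at 3 months, and the Val-CAC sum 11150, 13490 and 23100, against 15470, so only replicate 3 lay above the 3 month means. The most abundant valine members AS-tDR-007276, AS-tDR-000052 and AS-tDR-001449 had log2 differences of -0.50, -0.19 and -0.45 and did not pass (edgeR, adjusted p = 0.14, 0.651 and 0.221). All 18 arginine IDs were negative (median -0.77), and 13 of 15 threonine IDs (median -0.81; without 22 month replicate 3 the medians were -0.49 and -0.51), with 0 past the threshold in either list, also when adjusted over the list alone. For arginine, AS-tDR-001596, AS-tDR-008900 and AS-tDR-010792 had log2 differences of -0.95, -0.82 and -0.25. For threonine, AS-tDR-011549, AS-tDR-011551 and AS-tDR-011553, all of 1 Thr-CGT precursor, had -0.74, -0.72 and -0.81.

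Of the 20 lists only valine passed fry's directional test (adjusted p = 0.0156). Without 3 month replicate 1 the arginine list no longer passed camera with the preset correlation (adjusted p = 0.0852), and neither did threonine without 3 month replicate 2 (adjusted p = 0.124) or 22 month replicate 3 (adjusted p = 0.0715). The glycine list, with a median of 0.22, did not pass (adjusted p = 0.119), but did without 22 month replicate 1 (0.31, adjusted p = 0.0219) and with no filter on low counts (0.42, adjusted p = 0.0291), and its median lay between 0.17 and 0.51 with one library left out.

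Tags were also summed per anticodon, over the IDs that name 1 anticodon only. CPM of these sums are scaled to the total of those tags, not of all listed tags, and so lie higher than CPM of single IDs. AS-tDR-012735, the 1 ID of Ile-TAT, had a mean of 375 CPM at 22 months as a single ID and 523 as a sum. Sums for 4 of the 5 leucine anticodons rose, Leu-TAA from 24470 ± 2947 to 49660 ± 7649 CPM (SD, n = 3 each; log2 difference 1.02, SE 0.22), Leu-CAA by 1.09 on the log2 scale, Leu-TAG by 0.93 and Leu-AAG by 1.30. Asn-GTT rose by 1.15, and Ile-TAT, which has 1 ID, was listed at 0 at 3 months and reached 523 ± 83.5 at 22 months. Met-CAT fell by 1.43, from 81490 ± 1978 to 30160 ± 11580. These 7 of 42 sums passed (edgeR, adjusted p between 0.0245 and 0.0309). Leu-CAG did not (log2 difference 0.33, adjusted p = 0.532). No sum passed without 3 month replicate 1, 2 or 3, 17 passed without 22 month replicate 1, 3 without 22 month replicate 2 and 6 without 22 month replicate 3. With library size only 1 sum passed, with a replicate block 1, and when scaled to the smallest listed count 0. These repeats were chosen after seeing the data.

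**Figure D2:**
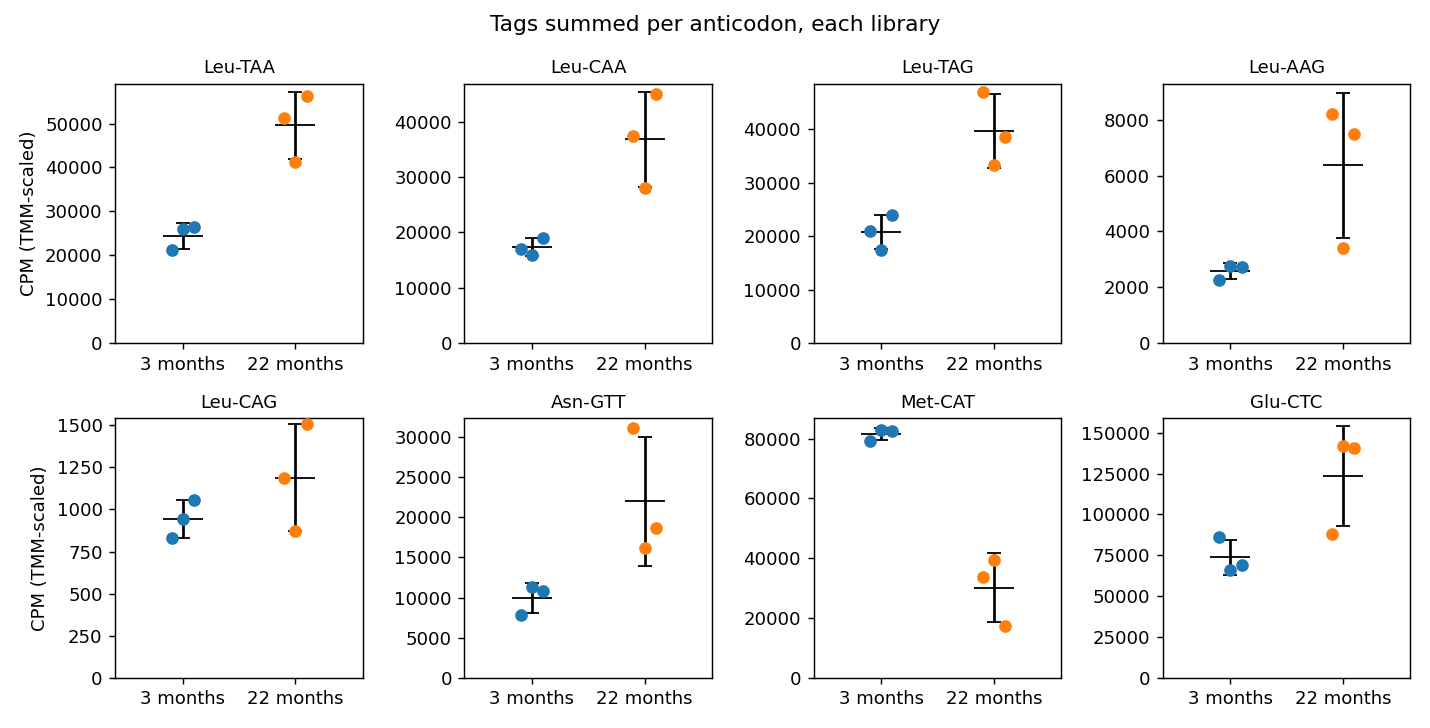
CPM summed per anticodon (vertical axis) in each library at 3 months (blue) and 22 months (orange), with mean and SD (n = 3). The Leu-TAA, Leu-CAA, Leu-TAG, Leu-AAG and Asn-GTT sums lie higher in every library at 22 months, and Met-CAT lower; Glu-CTC is also separated but did not pass the test.

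As shares of all listed tags, methionine fragments went from 6.43% ± 0.405 to 2.02% ± 0.878 (SD, n = 3 each), leucine from 7.41% ± 0.912 to 11.1% ± 2.72, asparagine from 0.788% ± 0.175 to 1.5% ± 0.78 and valine from 6.41% ± 0.597 to 4.76% ± 0.758. Of 20 amino acids, 4 were separated higher and 7 lower. The exact two-sided permutation test of 3 against 3 gave p = 0.1 for each of these, the smallest it allows, and 0.182 after adjustment over the 20.

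The series title singles out a fragment of glutamate tRNA that ageing induces. Fragment sequences are not given, so which ID is that fragment is not known here. The most abundant Glu-CTC ID, AS-tDR-001260, picked by its abundance alone, was at 9476 ± 450 CPM at 3 months and 15617 ± 3459 at 22 months (SD, n = 3 each), 1.65-fold higher and higher in 3 of 3 libraries. Its log2 difference of 0.72 (SE 0.22) did not pass edgeR's test (adjusted p = 0.0943). The DESeq2 test (adjusted p = 0.00445) was the only setting in which it passed. The most abundant Glu-TTC fragment, AS-tDR-001267, was at 8443 ± 678 and 7998 ± 1747 (log2 difference -0.08, SE 0.22; edgeR adjusted p = 0.853).

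Of 17 Glu-CTC IDs tested, 0 rose and 1 fell over all IDs, and adjusted over these 17 alone 6 rose and 2 fell. Adjusted over the list of 34 glutamate IDs, 4 of Glu-CTC and 2 of Glu-TTC rose and 2 of Glu-CTC fell. A set of 10 IDs is listed under one identical group of 12 parents of Glu-CTC tRNAs and precursors. In that set 7 IDs were higher in all 3 libraries at 22 months, up to a log2 difference of 1.93 for AS-tDR-000547 and 1.89 for AS-tDR-007519. The other 3 were negative, down to -1.35 for AS-tDR-011670, and 2 of them were separated. These 3 IDs were picked after their values were seen. The summed Glu-CTC level was 73750 ± 10830 and 123500 ± 30660 CPM (SD, n = 3 each), a log2 difference of 0.74 (SE 0.26; edgeR adjusted p = 0.07), and the Glu-TTC sum 38050 ± 3394 and 39270 ± 5890 (0.05, adjusted p = 0.856). The list of 34 glutamate IDs had a median of -0.09 and a mean of 0.20, which differ in sign, and did not pass camera (adjusted p = 0.781). All glutamate fragments together took 8.98% ± 0.728 of listed tags at 3 months and 10.7% ± 0.787 at 22 months (SD, n = 3 each; exact permutation p = 0.1). The Glu-CTC and Glu-TTC sums are scaled to the tags of IDs that name 1 anticodon only. They cannot be set against these shares or against CPM of single IDs. Which gene copy a fragment came from, and its place in the tRNA, were not determined.

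**Figure D3:**
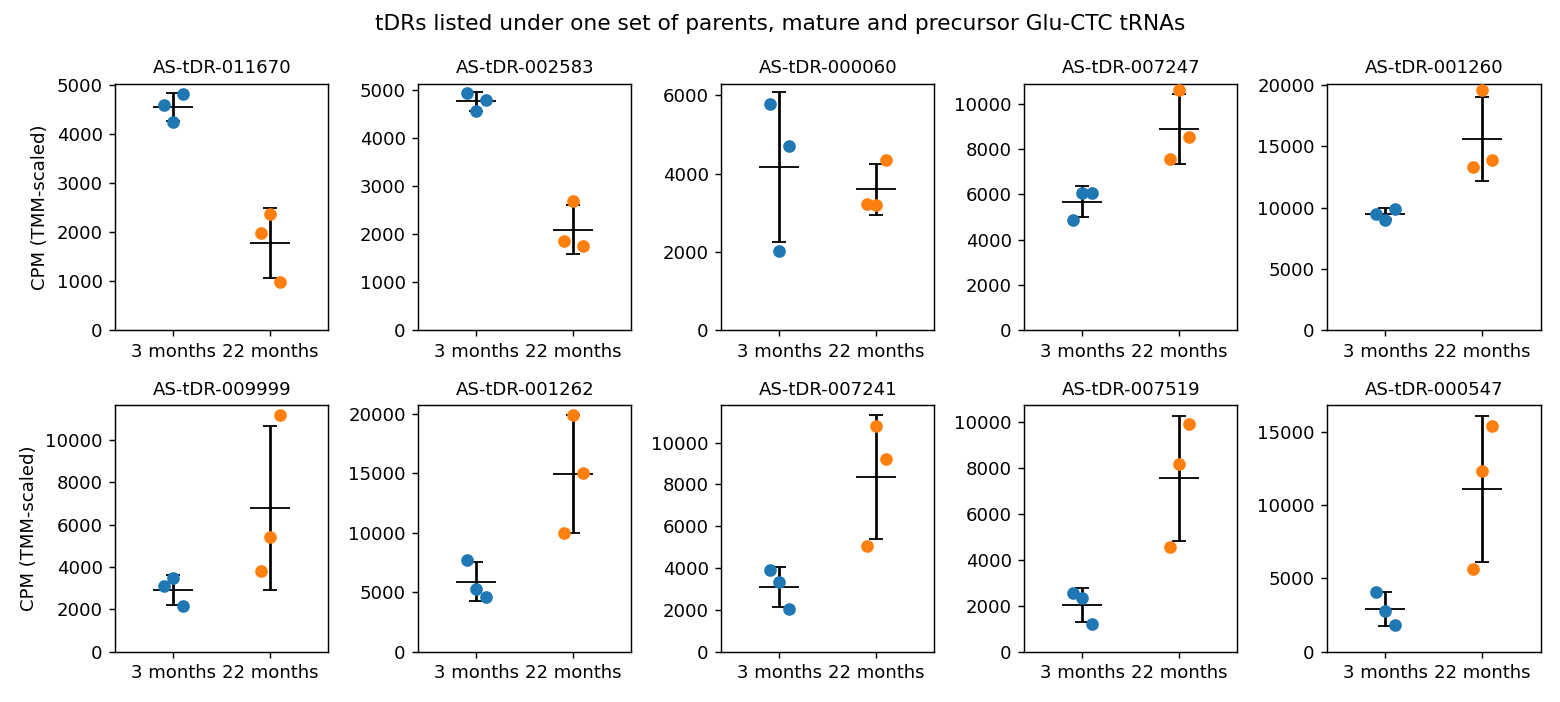
CPM (vertical axis) of the 10 tDRs listed under one set of 12 Glu-CTC parents, in each library at 3 months (blue) and 22 months (orange), with mean and SD (n = 3). In 7 of the 10, every library at 22 months lies above every library at 3 months.

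The libraries of one age were not equally alike. Spearman correlations across the 591 IDs, which are not independent of one another, lay between 0.87 and 0.916 within the 3 month group. At 22 months, replicates 1 and 2 correlated at 0.908, and replicate 3 at 0.749 and 0.824 with them. Between the ages, 22 month replicate 1 correlated at 0.852, 0.835 and 0.821 with 3 month replicates 1, 2 and 3. For 22 month replicate 2 these values were 0.891, 0.86 and 0.806. For 22 month replicate 3 they were 0.702, 0.636 and 0.577. Across all IDs each library thus correlated best with a library of its own age. The ages still did not form separate groups, since 22 month replicate 1 lay closer to every 3 month library than to replicate 3 of its age. Over the IDs above 0 in all 6 libraries, 22 month replicate 3 correlated at 0.85 and 0.877 with replicates 1 and 2 of its age. The highest value between the ages was then 0.875, for 3 month replicate 1 and 22 month replicate 2. Those of 22 month replicate 3 with 3 month replicates 1, 2 and 3 were 0.734, 0.69 and 0.601. In 22 month replicate 3, 218 IDs were at 0, against 132 and 178 in the other libraries of its age.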

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

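The repeats of the anticodon sums, the restriction to IDs above 0 in all 6 libraries, the raised zeros, the scaling to the smallest listed count and TMM scaling of sums were chosen after seeing the data. The 29 IDs past the threshold, 21 higher and 8 lower, became 44 with DESeq2 size factors (15 lower), 97 with the DESeq2 test (59 higher, 38 lower), 46 with limma-voom (20 lower), which hold 19 of the 29, and 7 sums per anticodon (6 higher, 1 lower). They became 0, with 0 higher and 0 lower, by edgeR with library size only, with no filter on low counts and when scaled to the smallest listed count; 107, 127 and 98 IDs then had an unadjusted p under 0.05. Among IDs above 0 in all 6 libraries 65 passed (38 higher, 27 lower), and 84 with zeros raised to 1 below the smallest listed count (53 higher, 31 lower). With one library left out, 0 to 14 passed, 0 to 9 higher and 0 to 7 lower, and of the 29 these hold 12 without 22 month replicate 2 and 8 without 22 month replicate 3. All 29 kept their sign in every setting that tested them, 23 being tested among IDs above 0 in all libraries. Library size only moved the median log2 difference of all IDs from -0.155 to -0.34, and scaling to the smallest listed count to -0.308. The 6 amino acid lists became 0 with an estimated correlation, 1 by fry's directional test and 13 by its mixed test, and were 5 to 8 with one library left out. After summing per anticodon, 1 of only 7 lists passed, and asparagine and methionine had too few anticodons to form a list. The 7 anticodon sums became 1 with library size only, 0 when scaled to the smallest listed count, and 0 to 17 with one library left out. AS-tDR-001260 passed with the DESeq2 test only, at 0.73 (adjusted p = 0.00445, range over its settings up to 0.32).

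Directions turned only for values that had not passed, the valine list excepted, whose median was 0.041 after summing per anticodon, where IDs shared between anticodons are left out and Val-AAC and Val-CAC lay above their 3 month means in 22 month replicate 3 only. The lysine sum was 0.96 without its most abundant fragment, 0.14 with TMM scaling, and between -0.19 and 0.012 with one library left out. With one library left out, the median of the glutamate list lay between -0.15 and 0.12, AS-tDR-001267 between -0.15 and 0.15, AS-tDR-010792 between -0.37 and 0.064, AS-tDR-000052 between -0.29 and 0.026, and the Glu-TTC sum between -0.19 and 0.16. Library size only gave -0.043 for AS-tDR-011859 and -0.18 for the Glu-TTC sum, and scaling to the smallest listed count -0.0091 and -0.16. The cause was not tested in any of these cases.

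The labels do not state that replicate numbers pair these samples. Deviations of same-numbered libraries correlated at -0.459, 0.0366 and -0.341, and 2 of 6 libraries correlated best with their own number. With 3 libraries per age, these values cannot decide whether the numbers pair the samples. With a replicate block 0 IDs passed, 0 higher and 0 lower (78 at an unadjusted p under 0.05), and 1 anticodon sum. Sums as a share of tRNA fragment signal equal the sums given, since every listed ID is a tRNA fragment. The other pseudocounts planned for normalized values were not run, since the values are counts. The fitted log2 difference of an ID at 0 in one age depends on how zeros are treated: for AS-tDR-001808 it was 1.95 with raised zeros, against 8.29. The lists by fragment end, length, RNA class and cell type gave no value.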

Other observations

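The restriction to IDs listed in all libraries, the lists by precursor or mature parent and the tests of causes were chosen after the results were seen, and every bound that decides a cause, those for the splits included, was written down only after its value, or a closely related one, was known; the left-out library and 2 of the 3 other scalings were planned as alternatives, not as tests of causes. Among the 290 IDs above the listing minimum in all 6 libraries, 38 rose and 27 fell (edgeR, adjusted p under 0.05). Rises comprised 18 of leucine, 6 of asparagine, 6 of glutamate, 3 of alanine, 2 of glycine and 1 each of histidine, lysine and valine. Falls comprised 7 of valine, 6 of methionine, 3 each of arginine and aspartate, 2 each of glutamate and threonine and 1 each of glutamine, glycine, serine and tyrosine. The glutamate rises were AS-tDR-000547, AS-tDR-007519, AS-tDR-007241 and AS-tDR-001262 of Glu-CTC, by 1.96, 1.90, 1.44 and 1.35 on the log2 scale, and AS-tDR-000586 and AS-tDR-007221 of Glu-TTC, by 1.59 and 1.12. AS-tDR-002583 and AS-tDR-011670 of Glu-CTC fell by 1.21 and 1.39. All of these but AS-tDR-002583 fall outside the naming rule and were chosen after their values were seen.

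Fragments listed under precursor names only stood lower at 22 months, with a median log2 difference of -0.72 over 62 IDs (camera, adjusted p = 0.00398; adjusted p = 0.418 with an estimated correlation), of which 1 rose and 3 fell. Those of mature names only had a median of -0.01 over 119 IDs, of which 8 rose and 0 fell (adjusted p = 0.119), and those of both kinds -0.13 over 258 IDs, of which 12 rose and 5 fell (adjusted p = 0.666). Precursor IDs went both ways among IDs above 0 in all libraries. AS-tDR-011559 and AS-tDR-011561 of an Ala-CGC precursor had log2 differences of 0.84 and 0.54. AS-tDR-011549 of a Thr-CGT and AS-tDR-008900 of an Arg-ACG precursor had -0.77 and -0.85. Both also belong to the threonine and arginine lists above. Those lists and the precursor IDs share members and are not separate observations. The Ala-CGC IDs fall outside the naming rule and were chosen after their values were seen.

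Leucine fragments higher at 22 months may reflect age, and 4 technical causes were set against it. Overlapping fragments of one tRNA counted many times would raise 1 anticodon. Sums of 4 of the 5 leucine anticodons were higher in every library at 22 months. Such separation was common, at 39.4% of tested IDs in one direction or the other. No sum passed with any 3 month library left out, so the 4 sums argue only weakly against this cause. Without 22 month replicate 3 the median of the list was 0.924, so that library alone is not the source. The lowest median under 3 other scalings was 0.672, but these moved the median of all IDs by up to 0.185 and full library totals are not used here, so scaling stays open as part of the rise. Over the 41 leucine IDs above 0 in all libraries, 2 libraries of one age differed in the median by up to 0.418, against 0.762 between the ages, so a gradient between libraries stays open as well. Age and any difference in preparation between the 2 age groups also stay open, and the list did not hold with an estimated correlation.

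The 22 month replicate 3 stood apart from the other libraries. Low depth would place its listed total among the lowest, and its rank is 2 of 6. That rank covers listed tags only and, with full library totals not used here, cannot settle the depth of the whole library. A wrong age label would bring 22 month replicate 3 closest to a 3 month library. Its lowest correlation with the other 22 month libraries exceeded its highest with a 3 month one by 0.0474 (bootstrap SE over IDs 0.0196). That comparison starts from replicate 3 only, and across all IDs 22 month replicate 1 lay closer to every 3 month library than to replicate 3. A difference between animals or in RNA handling could explain why replicate 3 stood apart and was not tested.

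Log2 differences of Glu-CTC fragments had both signs, although over all IDs 0 rose and 1 fell. The 10 IDs of identical parents cannot be assigned to a gene copy, so differences between gene copies stay open. A gradient between libraries, such as in RNA handling, might also sort them: the difference between 2 libraries of one age was correlated, over these 10 IDs, with the age difference taken from the other 4 libraries. The pairs of replicates 1 and 2, 1 and 3, and 2 and 3 gave r = -0.0853, 0.724 and 0.696 at 3 months and -0.642, -0.751 and -0.529 at 22 months (smallest size 0.0853), against 0.275, 0.33, 0.126, -0.199, -0.378 and -0.235 over all 290 IDs above 0 in all libraries. With 1 pair near 0, 3 libraries per age and overlapping IDs, neither this gradient nor age is excluded.

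The 6 libraries form 10 splits into 3 and 3, too few for a share under 0.05. The age split gave 29 IDs, 6 lists, 7 anticodon sums and, among IDs above 0 in all libraries, 65 IDs past the threshold, and the highest other split gave 0, 5, 0 and 0. In each case 1 of the 10 splits, the age split, reached the real count.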
